A study of Mus musculus with 768 samples.

How the data were processed

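The data are 768 single-cell libraries of mouse endothelial cells. Per the labels, cells negative for CD45 and positive for CD31 were sorted into plates by flow cytometry, after leukocytes and EpCAM-positive cells had been depleted with beads. MECA-79-positive cells came from lymph node (LN_HEV, plates pool1 and pool2) and from PyMT tumours (TU_HEV, pool3 and pool4), and MECA-79-negative cells from PyMT tumours (TU_EC, poolA to poolD). Each of the 8 plates held 96 wells. Libraries were made with Smart-seq2, which copies whole transcripts without molecular identifiers, with 23 PCR cycles, and read as 75 bp single ends on a NextSeq 500. Libraries of pool1 to pool4 share 1 series of library numbers and 1 file, and those of poolA to poolD another, so a difference between these sets of libraries and TU_EC cannot be told apart. No label names a sequencing run. No label names an animal, so each group was treated as 1 sample.

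The deposited files hold a raw count of reads per gene and cell, per the labels. The processing notes of the submitters name FastQC 0.11.4, STAR 2.4.1b and Subread 1.4.6-p2 with the genome build mm10 (GRCm38). The gene annotation, the strand setting and who handled which animals are not given in the sources used here. Both files list 51826 features, and 91 repeated symbols were summed to leave 51734. Of these, 47624 (92.1%) were found in GENCODE mouse release 21, from which chromosome positions were taken.

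Cells were kept with at least 50000 counts, at least 1000 genes with a count and at most 30% of counts in the 37 mitochondrial genes. At least 2 of the 5 pan-endothelial genes (Pecam1, Cdh5, Tie1, Egfl7, Eng) had to reach 10 CPM (counts scaled by the total of the cell or group). Fewer than 3 of the 6 genes of each contaminant list (leukocyte, epithelial and tumour, mural and fibroblast) could do so. The read filters kept 159, 101 and 309 cells of LN_HEV, TU_HEV and TU_EC, and the endothelial rule left out 8, 3 and 6 of them, which leaves 151, 98 and 303. No program for calling doublets was used, since cells were sorted singly into wells, and the contaminant rule stood in its place. Retained cells summed to 168656564 counts in LN_HEV, 146215450 in TU_HEV and 221773977 in TU_EC. A floor of 3 counts over a group corresponds to 0.0178, 0.0205 and 0.0135 CPM. Across genes, Spearman coefficients between plate sums were 0.843 for the LN_HEV plates, 0.834 for the TU_HEV plates and 0.884 to 0.900 for the TU_EC plates. Genes are not independent replicates. Ribosomal RNA features took 16.1%, 9.36% and 31.6% of counts.

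Counts were summed over the cells of a group, scaled to CPM by the total, and compared as ratios with exact Poisson intervals. No test or count of changed genes was made, since there are no replicates. A group at 0 counts was set to the floor and its ratio given as a bound. Exact 95% lower limits of such ratios were lower than these bounds, such as 5900 against 7255 for Lrp2. The 21 gene lists and 9 marker lists were summarised by the median log2 ratio of members with at least 3 counts in a group. Each median has its percentile among 10000 random lists of the same size drawn from 20 bins of expression, and its range over pairs of plates. The gene lists were MECA-79 epitope synthesis, HEV mucins and addressins, other lymph node HEV genes, LTbR and NF-kB signalling, venous and leukocyte adhesion, arterial, capillary, tip cell and angiogenic, basement membrane and matrix, interferon-stimulated, MHC class I and class II presentation, chemokines and decoy receptors, proliferation, hypoxia and glycolysis, Notch pathway, VEGF and angiopoietin receptors, junctions, TGF-beta and mesenchymal transition, immune regulatory ligands, and immediate early and heat shock genes. The marker lists were pan-endothelial, leukocyte, T cell, B cell, myeloid, epithelial and tumour, mural and fibroblast, lymphatic, and erythroid and platelet.

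Genes were named by a rule. For each comparison with TU_HEV the 12 genes with the largest ratio each way were named, and for LN_HEV against TU_EC 6 each way. They needed at least 50 CPM in the higher group, a count in at least 30% of its cells and a ratio of at least 2 the same way in every pair of plates. Gene models without a proper symbol and mitochondrial, ribosomal protein, immunoglobulin, T cell receptor and haemoglobin genes were left out. Members of the gene lists could be named as well. The groups, comparisons, filters, lists and this rule were set before the data were examined.

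For the position of TU_HEV, genes at least 4-fold apart and at 20 CPM or more in the higher group were chosen on pool1 against poolA with poolB. Their log2 ratios were then measured on the other plates. For shares, each cell was thinned to 100000 counts with seed 1, and 4 cells (1 of LN_HEV, 3 of TU_EC) were too shallow. Correlations across TU_HEV cells used thinned counts as log2(CPM + 10), per plate, with 1000 random lists. Clusters were found in each group by itself, on all cells that passed the read filters and before the endothelial rule, with 1500 variable genes, 15 principal components, 15 nearest neighbours and the Leiden method at resolution 1. A cluster was named only from fixed marker lists with at least 3 members 2-fold higher, where its leading genes bore the name out. A library was taken to hold another when it had at least as many counts at 95% or more of the other's genes, for libraries with at least 500 genes. The 2 ribosomal RNA features are CT010467.1 and AY036118.

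Alternatives changed 1 choice at a time: equal weight per cell, median-of-ratios size factors, totals without the 20 highest genes of any group (30 genes in all), stricter and looser filters, no endothelial rule, a further marker filter, thinned cells, each plate left out, low members left out, and other choices for positions, shares and clusters. Leaving out the holding libraries, leaving out the ribosomal RNA features and restricting the genes of the position were added later. Simulated counts checked the code. With 200 changed genes, set ratios of 2, 4 and 16 were estimated as median log2 ratios of 0.97, 1.96 and 4.04 for TU_HEV against LN_HEV. These estimates were taken relative to the median of the unchanged genes, while the gene ratios in the results were not corrected for such a shift. A set position of 0.5 was estimated as 0.510 and 0.488, and 5 of 5 made pairs of holding and held libraries were found with 0 others. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.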

Results

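High endothelial venules (HEVs) are the blood vessels through which lymphocytes leave the blood, and vessels of the same kind form in some tumours. The antibody MECA-79 binds the sulfated glycans on their surface that capture lymphocytes. Single endothelial cells were sequenced from 3 gates: MECA-79-positive cells of lymph node (LN_HEV), MECA-79-positive cells of PyMT tumours, a mouse model of breast cancer (TU_HEV), and MECA-79-negative endothelial cells of PyMT tumours (TU_EC). LN_HEV and TU_HEV came from 2 plates of 96 wells each and TU_EC from 4. The filters on reads, genes and cell type kept 78.6%, 51.0% and 78.9% of the wells, or 98 cells of TU_HEV. The median total per retained cell was 1065764 counts in LN_HEV (range 96741 to 5044512), 1431389 in TU_HEV (276667 to 4002554) and 625611 in TU_EC (58737 to 2216188). Under 50000 counts were found in 24 wells of LN_HEV, 72 of TU_HEV and 27 of TU_EC. The labels name no animal, so each group was 1 sample with no replicates, and values are given without tests. Intervals are 95% intervals for counting error only, and reads copied by PCR without molecular identifiers are not independent molecules.

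**Figure D1:**
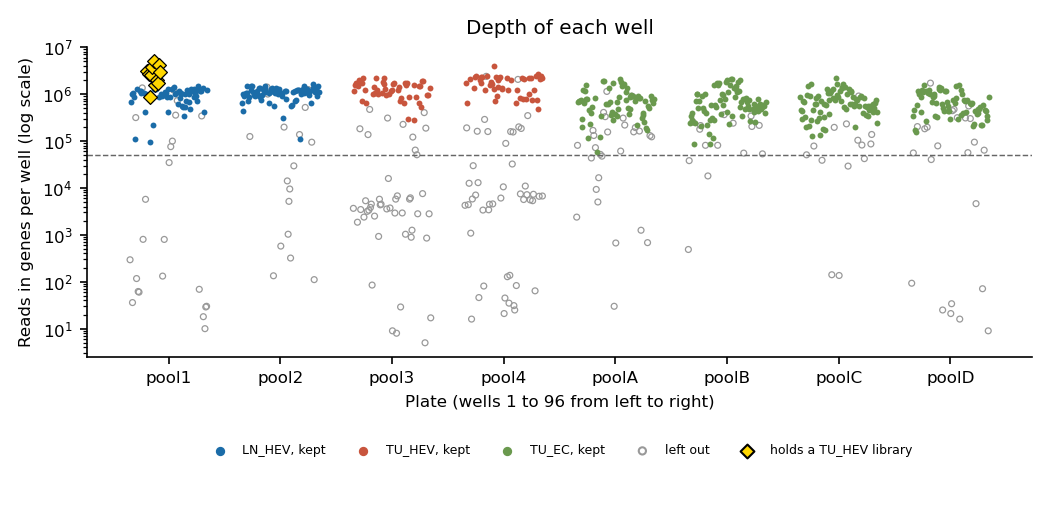
Total counts per well (log scale) on the 8 plates, coloured by group, with the filter at 50000 counts as a dashed line and the 11 libraries of pool1 that hold the counts of a TU_HEV library as gold diamonds. The median of those 11 libraries was 2699260 counts, against 1022444.5 for the other endothelial cells of the plate.

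Among LN_HEV libraries, 11 from the plate pool1 held nearly all counts of 19 TU_HEV libraries, gene by gene (the holding libraries). Capillary genes such as Cd36, a fatty acid receptor, stood at 237.5 CPM in LN_HEV and at 1.93 CPM without these libraries. Every retained cell was kept in the results, and values without the holding libraries are given beside ratios and medians of LN_HEV that they moved by over 1.5 times. The median log2 ratio of all genes at 20 CPM or more was 0.28 for TU_HEV against LN_HEV, 0.40 for TU_HEV against TU_EC and 0.15 for LN_HEV against TU_EC. Many list medians are therefore also given relative to these shifts, and those given alone include the shift. Random lists of matched expression carry the same shift. A feature annotated as ribosomal RNA, CT010467.1, took 120974 CPM in LN_HEV, 71429 in TU_HEV and 239097 in TU_EC.

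TU_HEV against LN_HEV asks how far the MECA-79-positive cells of a tumour carry the expression of a lymph node HEV. The tumour cells held far less of the lymph node HEV genes Glycam1, Ccl21a and Fut7. They kept part of Chst4, the sulfotransferase that makes the MECA-79 epitope. They held more of the venous adhesion genes Selp and Sele, of basement membrane genes such as Col4a1, of tip cell genes such as Nid2 and of interferon-stimulated genes such as Irf1.

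Glycam1, a secreted sialomucin ligand of L-selectin (chromosome 15 from 103562759 to 103565081 in GRCm38), stood at 56369 CPM in LN_HEV. In TU_HEV it stood at 127.7 CPM (interval 125.9 to 129.5), 441-fold lower. Ccl21a, the CCR7 ligand that arrests lymphocytes on the vessel wall (chromosome 4 from 42772860 to 42773993), stood at 16551 CPM in LN_HEV and at 0.376 CPM (55 counts) in TU_HEV. That was a 44001-fold difference (interval 33804 to 58408), although Ccl21a has near-identical copies in the mouse genome, so its counts are uncertain. Of the TU_HEV counts, 52 were in pool4 and 3 in pool3. Fut7, the fucosyltransferase that completes the L-selectin ligand (chromosome 2 from 25423267 to 25426374), was 51.3-fold lower in TU_HEV, at 18.4 against 944 CPM. Chst4 (chromosome 8 from 110029153 to 110039740) was 4.78-fold lower, at 206.98 against 989.6 CPM. Gcnt1, a glycan-branching enzyme, was 24.2-fold lower, and the sialyltransferase St3gal6 was 2.11-fold lower. B3gnt3, another enzyme of glycan synthesis, went the other way, at 88.7 CPM in TU_HEV and 46.9 in LN_HEV. The list named MECA-79 epitope synthesis holds 8 genes, and the sort gate bears on it through Chst4. The list is wider than the epitope itself, since it also holds Fut7, Gcnt1 and St3gal6. The median log2 ratio of the list was -1.79, or -2.06 relative to all genes. It was -2.33 to -1.10 over the plate pairs and -1.94 without the holding libraries, and lay at percentile 0 of the random lists. Without pool2 this median was -1.18. In this list 6 of 8 measured members were at least 2-fold lower in TU_HEV.

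The 12 genes named by rule as higher in LN_HEV included Lrp2, an endocytic receptor. Lrp2 stood at 148.9 CPM in LN_HEV and had 0 counts in TU_HEV, at least 7255-fold lower against a floor of 3 counts over the group. The sialomucin gene Parm1 was at least 4793-fold lower, the guidance receptor Robo2 at least 4731-fold and the semaphorin Sema5a at least 3832-fold. Dclk1, a kinase of the microtubule cytoskeleton, had 350.2 CPM in LN_HEV and 3 counts in TU_HEV, a ratio of 17067 (interval 5839.6 to 82760.03). Ggt5, which converts leukotrienes, stood at 244.6 CPM in LN_HEV with 1 count in TU_HEV, and the prostaglandin D synthase Ptgds stood at 192.2 CPM with 1 count. The surface glycoprotein Cd24a had 175.2 CPM and 1 count, and the neurofilament gene Nefh had 144.6 CPM and 2 counts. The collagen receptor Ddr2 was 3833-fold lower in TU_HEV (interval 1497 to 14068). These ratios rest on the cells kept: with the 3 TU_HEV cells that the endothelial rule left out, and those of LN_HEV, Robo2 was 70.0-fold lower, Sema5a 87.3-fold, Ddr2 64.7-fold and Ggt5 848-fold. Without the holding libraries 11 of these 12 genes were named again.

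Of other HEV genes, Enpp2, which makes lysophosphatidic acid for lymphocyte transmigration, was 7.99-fold lower in TU_HEV, at 391 against 3122 CPM. Apoe, a lipid carrier, was 7.22-fold lower. Sphk1, which makes the lymphocyte egress signal sphingosine 1-phosphate, was 4.33-fold lower, while its exporter Spns2 was 2.19-fold higher. Ackr1, a decoy receptor of venules that carries chemokines across the wall, was 2.32-fold higher, at 2478 against 1069.8 CPM. Lrg1, a secreted glycoprotein of HEVs, lay at 4003 and 3965 CPM. The other lymph node HEV genes had a median of -1.05 (-1.33 relative to all genes, percentile 0), with 4 of 8 measured members at least 2-fold lower and 2 at least 2-fold higher. The 6 HEV mucins and addressins went both ways: Glycam1 and Parm1 were lower, while Podxl, an anti-adhesive sialomucin, was 5.38-fold higher. Their median was -0.39, and 0.22 without the holding libraries. It was also positive with equal weight per cell (0.02), in thinned cells (0.06), without pool1 (0.25) and without pool4 (0.04), so its sign was not settled. Relb and Nfkb2, the transcription factors of the lymphotoxin pathway that maintains HEVs, were 1.97-fold and 1.66-fold lower in TU_HEV. Tnfaip3, a feedback inhibitor of NF-kB, was 3.15-fold higher. The LTbR and NF-kB list had a median of 0.20 (-0.08 relative to all genes, percentile 32.0) and turned negative at -0.05 under size factors, -0.11 without the 20 highest genes and -0.04 without pool1.

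Selp, the P-selectin of inflamed venules, stood at 2785 CPM in TU_HEV against 449.6 in LN_HEV. The ratio was 6.19, and 94.7 without the holding libraries. Its plates differed, with 863 CPM in pool1 and 35.4 in pool2. Sele, the E-selectin, was 4.98-fold higher in TU_HEV, or 38.7-fold without the holding libraries. The adhesion receptor gene Vcam1 was 2.99-fold higher, or 5.66-fold without them. Vwf, which tethers platelets, was 4.53-fold higher, or 11.6-fold without them. The venous and leukocyte adhesion list had a median of 0.95 (0.67 relative to all genes; 0.68 to 1.26 over plate pairs), at percentile 99.2, with 5 of 10 measured members at least 2-fold higher.

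The 12 genes named as higher in TU_HEV were led by Gpihbp1, the capillary anchor of lipoprotein lipase, at 427 against 10.1 CPM. Its ratio was 42.3 (interval 40.3 to 44.5), and 257.4 without the holding libraries. Cdh13, the receptor of adiponectin, was 35.2-fold higher (642-fold without them). The laminin gene Lamb1 was 20.1-fold higher (69.0-fold without them) and Fscn1, which bundles actin in migrating cells, 18.8-fold (25.0-fold). Rgcc, a hypoxia-responsive regulator of the cell cycle, was 15.0-fold higher, and at least 8569.8-fold without the holding libraries, where LN_HEV had 0 counts. C1qtnf9, Lmcd1, Mid1, Sema6d, Mest, Ext1 and Dusp2 completed the 12, at ratios from 12.8 to 14.8. Their ratios without the holding libraries were 183.3 for C1qtnf9, 46.1 for Lmcd1, 31.2 for Mest, 25.9 for Mid1, 22.0 for Dusp2, 19.0 for Ext1 and 15.3 for Sema6d. Plates moved these ratios as well: without pool2 Gpihbp1 was 22.4-fold higher, Cdh13 18.5-fold, Lamb1 10.1-fold, Rgcc 7.51-fold, C1qtnf9 7.95-fold and Mid1 8.94-fold. Without pool1, which has the holding libraries, log2 ratios rose instead. Gpihbp1 went from 5.40 to 8.59, Mest from 3.79 to 7.70, and Lamb1 from 4.33 to 12.4 with LN_HEV at the floor. Without pool4 Sema6d was 6.35-fold and Dusp2 6.62-fold higher, and with equal weight per cell Mest was 2.91-fold higher. Of the 12, only Rgcc was named by the rule without the holding libraries. Other genes then named included Car4, a capillary carbonic anhydrase, at 289.8 CPM in TU_HEV, and Il6, a cytokine, at 276.1 CPM, both with 0 counts in the other LN_HEV libraries, so that Car4 was at least 13751-fold higher and Il6 at least 13101-fold. With all libraries the ratio of Car4 was 6.81 and that of Il6 was 6.45. Hdc, which makes histamine, stood at 314.9 CPM with 4 counts in those libraries, and the transcription factor gene Prdm1 at 125.9 CPM with 0 counts.

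**Figure D2:**
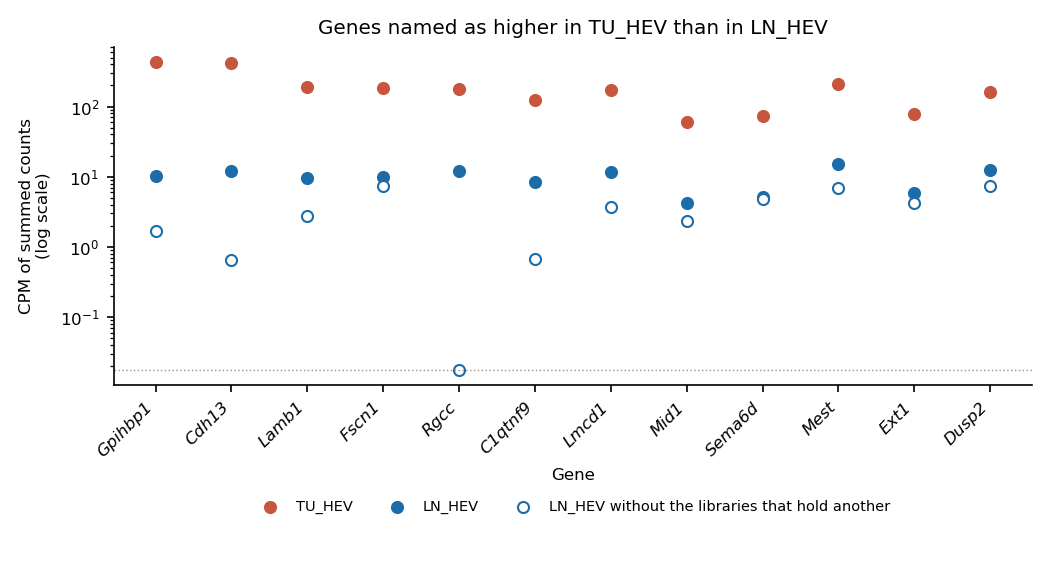
CPM of summed counts (log scale) of the 12 genes named as higher in TU_HEV than in LN_HEV. Shown are TU_HEV (red), LN_HEV (blue) and LN_HEV without the 10 kept libraries that hold another (open). The floor of LN_HEV at 0.0178 CPM is dotted. For Gpihbp1 the values were 427, 10.1 and 1.66 CPM.

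Capillary genes as a group had a median log2 ratio of 2.83 (2.55 relative to all genes, percentile 100), and 7.20 without the holding libraries, with 9 of 10 measured members at least 2-fold higher. Cd36 was 11.0-fold higher in TU_HEV and Fabp4, a fatty acid carrier, 9.76-fold. Without the holding libraries these ratios were 1353 and 83.8. Tip cell and angiogenic genes had a median of 4.6 (4.32 relative to all genes), with 9 of 10 measured members at least 2-fold higher and a range of 1.56 to 5.57 over plate pairs. Without pool4 their median was 2.15. Esm1, a proteoglycan secreted by tip cells, stood at 39.6 CPM and had 0 counts in LN_HEV, at least 2224-fold lower. Nid2, a basement membrane nidogen, was 30.4-fold higher and the potassium channel subunit Kcne3 57.2-fold. All 11 measured basement membrane and matrix genes were at least 2-fold higher, with a median of 2.26 (1.98 relative to all genes). Col4a1, a type IV collagen chain, stood at 1569 against 327.03 CPM, or 206.7 without the holding libraries. Of arterial genes 7 of 8 measured were at least 2-fold higher (median 2.33, 2.05 relative to all genes, and 2.99 without the holding libraries). Hey1, a Notch target of arteries, stood at 53.6 against 0.883 CPM, or 0.148 without them.

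Interferon-stimulated genes had a median of 2.05 (1.77 relative to all genes, percentile 100) with 13 of 14 measured members at least 2-fold higher. Over plate pairs the median was 1.73 to 2.4. Irf1, a transcription factor induced by interferon gamma, was 3.59-fold higher in TU_HEV, Iigp1, a GTPase of the same response, 5.52-fold, and Cxcl10, a T cell chemokine, 4.08-fold. Without the holding libraries these ratios were 6.54, 10.7 and 15.9. Genes of MHC class II presentation had a median of 1.47 (1.2 relative to all genes, and 2.16 without the holding libraries), while MHC class I presentation had 0.44 (0.16, percentile 69.1). B2m, the light chain of MHC class I, lay at 6391 and 6229 CPM. The chemokine list had a median of 1.78, and 2.78 without the holding libraries, but ran from -0.28 to 3.25 over plate pairs. Cxcl9, another T cell chemokine, was 10.7-fold higher in TU_HEV, or 34.3-fold without them. The immune regulatory ligands had a median of 1.25, or 1.84 without them, and Nt5e, which makes adenosine, was 9.12-fold higher.

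The Notch pathway list had a median of 1.30 (1.02 relative to all genes), and the receptor gene Notch4 was 8.72-fold higher in TU_HEV. The TGF-beta list had 0.98 (0.70 relative to all genes) and the VEGF and angiopoietin receptors 0.95 (0.67). The junction genes had 0.58 (0.31, percentile 83.2). Jam3, a junctional adhesion molecule, was 4.12-fold lower in TU_HEV, against the direction of its list. Proliferation genes had a median of 1.49, with plate pairs from 0.63 to 5.46, and Ccnb2, a mitotic cyclin, stood at 11.0 against 1.78 CPM. The hypoxia list had 0.67 (0.39 relative to all genes, percentile 92.0). The immediate early and heat shock list, a sign of handling, had 0.67 (0.39 relative to all genes), and Atf3 of this list was 5.63-fold higher, or 22.8-fold without the holding libraries. Markers of other cells had negative medians: -5.77 for leukocyte, -4.28 for T cell, -0.79 for B cell and -2.52 for myeloid markers. At least 2-fold lower in TU_HEV were 5 of 6 leukocyte, 3 of 5 T cell, 1 of 3 B cell and 2 of 4 myeloid markers. In the leukocyte and myeloid lists 1 marker each was at least 2-fold higher. Plate-pair medians reached 0.38 for T cell, 0.39 for B cell and 1.45 for myeloid markers. The erythroid and platelet markers had -14.65, but ran from -14.81 to -0.03 over plate pairs. The platelet factor Pf4 stood at 373.8 CPM in LN_HEV against 6.44. Mural markers had -0.24 (3.51 without the holding libraries), lymphatic markers -0.14 (0.84) and pan-endothelial markers 0.60. Most members of the leukocyte, T cell, B cell, myeloid and erythroid lists were at the floor in a group, so these medians depend on the floor.

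TU_HEV against TU_EC asks what sets MECA-79-positive cells apart from the other endothelial cells of the same kind of tumour. The MECA-79-positive cells held the HEV genes Chst4, Glycam1 and Enpp2, and more of the venous genes Selp, Vcam1 and Ackr1. They held more of the lipid uptake genes Cd36 and Fabp4 and of antigen presentation genes such as B2m. They held less of the tip cell genes Apln and Kcne3 and of the matrix gene Fn1. The labels put TU_EC in a separate set of libraries and a separate file, so a difference between these sets and the gate cannot be told apart.

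Chst4 stood at 206.98 CPM in TU_HEV and had 0 counts in TU_EC, at least 15301-fold lower. Glycam1 had 44 counts (0.198 CPM) in TU_EC and was 644-fold higher in TU_HEV (interval 479 to 886). Its log2 ratio of 9.33 became 8.76 with equal weight per cell and 10.2 without poolD. Fut7 had 0 counts in TU_EC, and TU_HEV was at least 1361-fold higher. Enpp2 was 21.4-fold higher, Apoe 10.7-fold, Ackr1 16.4-fold and Lrg1 7.89-fold. The epitope synthesis list had a median of 1.13 (0.73 relative to all genes; 0.80 to 1.99 over plate pairs), with 4 of 8 measured members at least 2-fold higher. Gcnt1 did not share the difference, at 8.47 and 8.54 CPM. The other lymph node HEV genes had a median of 3.20 (2.80 relative to all genes), with 6 of 8 at least 2-fold higher. Ccl21a of this list was 2992-fold lower in TU_HEV, at 1126 CPM in TU_EC, where it stood beside lymphatic markers. The mucin list had -0.19, with 2 members at least 2-fold higher and 2 lower.

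Lipg, the endothelial lipase, led the other named genes at 65.0 against 0.117 CPM, 554-fold higher in TU_HEV (interval 378.1 to 849). Car4 was 43.8-fold higher, and Ptafr, the receptor of platelet-activating factor, 32.7-fold. Serpinb1a, an inhibitor of neutrophil proteases, stood at 1509.9 against 60.7 CPM. Lifr, the receptor of leukaemia inhibitory factor, was 23.4-fold higher and the sulfotransferase Sult1a1 24.8-fold. C1s1, a complement protease, was 36.8-fold higher, and Dennd2d, a regulator of vesicle transport, 38.1-fold. Mctp1, a calcium sensor, was 21.8-fold higher and the hormone gene Fgf23 21.7-fold. Without pool3 Car4 was 19.8-fold and Fgf23 9.69-fold higher, and 24 of the 26 counts of Lipg in TU_EC were in poolB. With equal weight per cell Lipg was 103.2-fold higher, and without poolB Car4 was 157.4-fold higher. The log2 ratio of Fgf23 rose from 4.44 to 11.4 without poolC, with TU_EC at the floor. That of Lipg rose from 9.11 to 12.0 under the strict filter. Of capillary genes, Lpl, the lipoprotein lipase, stood at 147.1 CPM in TU_HEV and 0.0180 (4 counts) in TU_EC, with a count in 11.2% of TU_HEV cells. Cd36 was 14.6-fold higher in TU_HEV and Fabp4 6.71-fold. Gpihbp1 went the other way, at 1103 CPM in TU_EC. The capillary list had a median of 2.05 (1.65 relative to all genes), with 6 of 10 at least 2-fold higher.

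Venous and leukocyte adhesion genes had a median of 1.90 (1.51 relative to all genes; 1.29 to 2.48 over plate pairs), with 8 of 10 measured members at least 2-fold higher. Il1r1, the interleukin 1 receptor, was 13.4-fold higher in TU_HEV, Vcam1 11.3-fold, Selp 10.1-fold and Sele 8.95-fold. The LTbR and NF-kB list had 1.38 (0.98 relative to all genes, percentile 100). Its members Tnfaip3, Traf1 and Birc3, an inhibitor of cell death, were 8.30-fold, 7.28-fold and 5.42-fold higher.

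MHC class I presentation genes had a median of 1.44 (1.04 relative to all genes), with 9 of 9 at least 2-fold higher and plate pairs from 0.99 to 1.76. H2-K1, a heavy chain, was 2.71-fold higher, B2m 2.36-fold and the immunoproteasome subunit Psmb8 3.25-fold. The class II list had 1.82 (1.42 relative to all genes), and Cd74, its invariant chain, was 3.52-fold higher. Interferon-stimulated genes had 1.42 (1.02 relative to all genes), with 12 of 14 at least 2-fold higher. Ifit1, an antiviral effector, was 17.4-fold higher and Irf1 3.76-fold. The immune regulatory list had 1.2, and Tnfsf10, a death ligand, was 5.40-fold higher. In the chemokine list, with a median of -0.63, members split. Cxcl1, which recruits neutrophils, was 16.5-fold higher in TU_HEV, and Ackr3, a scavenging receptor, 4.64-fold lower. That median became positive at 0.21 in thinned cells and at 0.12 without pool4. Immediate early genes had 0.93 (0.53 relative to all genes).

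Tip cell and angiogenic genes had a median of -2.41 (-2.80 relative to all genes; -4.56 to -1.33 over plate pairs), with 9 of 10 measured members at least 2-fold lower in TU_HEV. Without pool4 the median was -4.25. Apln, the ligand of the apelin receptor, was 9.70-fold higher in TU_EC and Nid2 9.94-fold. Among the 12 genes named as higher in TU_EC, Col13a1, a transmembrane collagen, was 95.5-fold higher (interval 82.3 to 111.4). Fn1, the fibronectin gene, was 34.3-fold higher, at 518 against 15.1 CPM. Gpx3, a secreted peroxidase, was 22.1-fold higher and Flt4, the receptor of VEGF-C, 13.9-fold. Ppm1j, Fam102a, Emid1, Piezo2, Ramp3 and Nes completed the group. Most of these ratios depended on pool4, and without it Col13a1 was at least 2458-fold higher in TU_EC, Ppm1j at least 1126-fold, Fn1 1519.5-fold, Ramp3 50.7-fold, Piezo2 42.3-fold, Emid1 30.0-fold, Flt4 28.5-fold, Apln 23.3-fold and Nes 5.76-fold. Without pool3 Col13a1 was 53.3-fold higher, Fn1 19.3-fold and Ppm1j 17.5-fold. With the cells that the endothelial rule left out, Gpx3 was only 2.15-fold higher in TU_EC and Fn1 9.46-fold. The basement membrane list had a median of -1.0 (-1.40 relative to all genes), with 5 of 11 at least 2-fold lower. The arterial list had -1.02 (-1.42), and Gja4, a connexin of arteries, was 3.57-fold higher in TU_EC. Proliferation genes had -0.95 (-1.35), and Birc5, a mitotic survival factor, was 3.06-fold higher in TU_EC.

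Medians closer to 0 were found for hypoxia (-0.28), Notch (-0.46), the VEGF and angiopoietin receptors (-0.10, and 0.03 without pool3) and the TGF-beta list (-0.12, and 0.15 with equal weight per cell). Relative to all genes they were -0.68, -0.86, -0.50 and -0.52. Adm, a hypoxia-induced peptide hormone, was 6.88-fold higher in TU_EC, and the claudin gene Cldn5 2.55-fold. The junction list had a median of 0.02, which was -0.40 under size factors and -0.39 without ribosomal RNA. Lymphatic markers had a median of -6.22, and Mmrn1 of this list stood at 97.3 CPM in TU_EC with 0 counts in TU_HEV. Leukocyte markers had -5.90, erythroid and platelet markers -4.66, epithelial markers -1.87, mural markers -0.59 and myeloid markers -0.39. The only measured T cell marker had 0.88, the B cell markers 3.31 and the pan-endothelial markers 0.02. These medians depend on the floor as well, where most members of the leukocyte, B cell, myeloid, epithelial and erythroid lists lay in a group. The myeloid members went both ways, 2 higher and 2 lower.

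**Figure D3:**
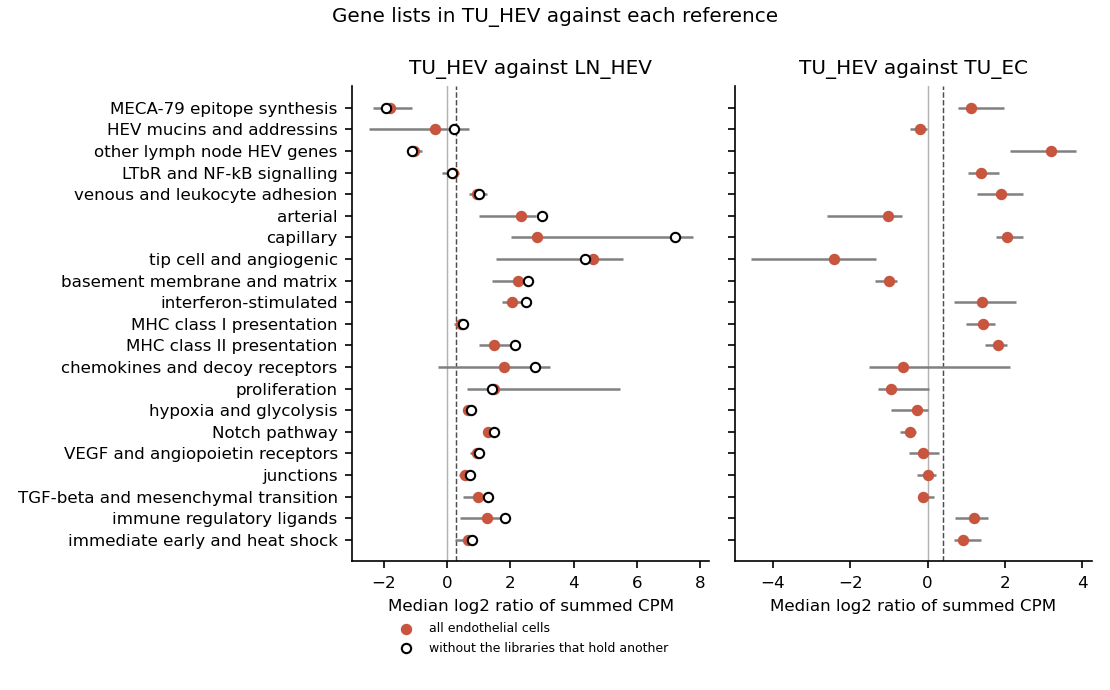
Median log2 ratio of summed CPM for each of the 21 gene lists (red) in TU_HEV against LN_HEV and against TU_EC. Grey bars run from the lowest to the highest plate-pair median. Open circles, drawn against LN_HEV only, are values without the 10 kept holding libraries. Dashed lines mark the median of all genes. MECA-79 epitope synthesis lay at -1.79 and 1.13, and tip cell genes at 4.6 and -2.41.

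LN_HEV against TU_EC sets the scale, since it compares the lymph node vessel with tumour endothelium outside the gate. LN_HEV cells were marked by Glycam1, Chst4 and Fut7, and TU_EC cells by the matrix gene Fn1 and the tip cell gene Esm1. Glycam1 was 284116-fold higher in LN_HEV (interval 211639.5 to 391021). Its log2 ratio of 18.1 became 17.6 with equal weight per cell and 19.0 without poolD. Chst4 was at least 73159-fold higher, Fut7 at least 69772-fold and Oit1, a secreted protein gene, at least 26316-fold. Dclk1 stood at 350.2 CPM with 1 count in TU_EC. Fn1 was 17470.1-fold higher in TU_EC (interval 7486 to 53805), with 5 counts in LN_HEV, and 276.7-fold with the cells that the endothelial rule left out. Emid1, a matrix protein gene, Esm1, and Piezo2, a mechanically gated channel, had 0 counts in LN_HEV and were at least 12472-fold, 10167-fold and 8726-fold higher in TU_EC. Cd109, a co-receptor of TGF-beta, and Clca2 were at least 6858-fold and 5059-fold higher. Without the holding libraries Ednrb, Prdm1 and Rgcc took 3 of these 6 places. The epitope synthesis list had a median of 2.69 (2.54 relative to all genes), the other lymph node HEV genes 3.42, the venous list 0.87 and MHC class I presentation 1.11. Interferon-stimulated genes had -0.45 and tip cell genes -7.56. Without the holding libraries the venous median was -0.06. The immune regulatory list reversed from 1.11 to -1.46 without them, and to -1.23 without pool1.

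The position of TU_HEV between both references was measured on genes chosen on pool1 against poolA with poolB, and read on the other plates, with 0 for the level of TU_EC and 1 for that of LN_HEV on a log scale. The holding libraries of pool1 carry counts of TU_HEV, so this choice was not independent of TU_HEV. Without them 81.1% of the genes high in LN_HEV were chosen again, and Selp, Sele, Vcam1, Car4 and Lpl were not. Genes high in lymph node HEVs lay closer to the middle than genes high in tumour endothelium, which lay nearer to TU_EC. The genes chosen as high in LN_HEV had a median position of 0.572, with quartiles at 0.233 and 0.870, of 0.568 in pool3 and 0.557 in pool4, and of 0.523 without the holding libraries. Chst4 lay at 0.829, Fut7 at 0.609 and Glycam1 at 0.483. Chst4 and Fut7 had 0 counts in TU_EC, so the lower end of their scale was the floor of 3 counts. Their positions therefore depend on depth and are not measured distances from a TU_EC level. Glycam1 had only 44 counts in TU_EC over all plates. Ccl21a lay outside the scale at -3.30, below TU_EC, and Ackr1 at 1.70, above LN_HEV. Lrg1 and Birc3 lay near the lymph node level, at 0.95 and 0.983, while Gcnt1 lay at 0.0160, near TU_EC. The 443 genes chosen as high in TU_EC had a median position of 0.280, with quartiles at 0.125 and 0.573. This was 0.396 in pool3 and 0.273 in pool4, and 0.186 without the holding libraries, where 730 genes were chosen. Positions were not corrected for the shift of all genes, and under size factors the medians of both sets of genes lay closer together. Lamb1 lay at 0.0895, Esm1 at 0.158, Col4a1 at 0.254 and Apln at 0.479. For Lamb1 and Esm1 the LN_HEV end of the scale was the floor.

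Shares of cells ask whether the lower HEV expression of TU_HEV was spread over its cells or held by a part of them. In TU_HEV fewer cells had Chst4 and Glycam1 than in LN_HEV, and more had Selp and Sele. Cells were thinned to 100000 counts, and shares carry exact Clopper-Pearson intervals. Chst4, whose product makes the epitope used for sorting, had at least 2 counts in 98% of 150 LN_HEV cells and 41.8% of 98 TU_HEV cells (interval 31.9 to 52.2). It had them in 0 of 300 TU_EC cells, which allows up to 1.0% (3 of 300 cells), or 1.22% by the exact interval. Glycam1 was found in 100%, 18.4% (interval 11.3 to 27.5) and 0.667% of cells. Without thinning, the Glycam1 share of TU_HEV was 30.6%, but only 19 of its cells had 10 or more counts, and 51 had 0. TU_HEV wells under 50000 counts, which held 25 counts of Pecam1 over 72 wells, had up to 4 counts of Glycam1, apart from 1 well with 64. Fut7 was found in 95.3% of LN_HEV cells, 7.14% of TU_HEV cells and 0 TU_EC cells. Ccl21a was found in 79.3% of LN_HEV cells, 1 TU_HEV cell and 3.33% of TU_EC cells. Selp was found in 19.3% of LN_HEV cells, 76.5% of TU_HEV cells (interval 66.9 to 84.5) and 14% of TU_EC cells. Sele was found in 12%, 58.2% and 11.7%, and Vcam1 in 54%, 64.3% and 12.7%. The LN_HEV shares include 10 holding libraries, which carry counts of TU_HEV. Selp and Sele were among the leading genes of the LN_HEV cluster of 17 cells with the 11 holding libraries. Their LN_HEV shares may therefore be too high. Ackr1 was found in 91.3%, 67.3% and 10%, and Madcam1, the gut addressin, in 4.67%, 4.08% and 0.333%. Of 14 epitope and mucin genes the median cell held 9 in LN_HEV, 5 in TU_HEV and 4 in TU_EC. Among TU_HEV cells 10 had both Chst4 and Glycam1, 31 had Chst4 alone, 8 had Glycam1 alone and 49 had neither. All 41 cells with Chst4 also had Selp, and 34 cells had Selp without Chst4.

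**Figure D4:**
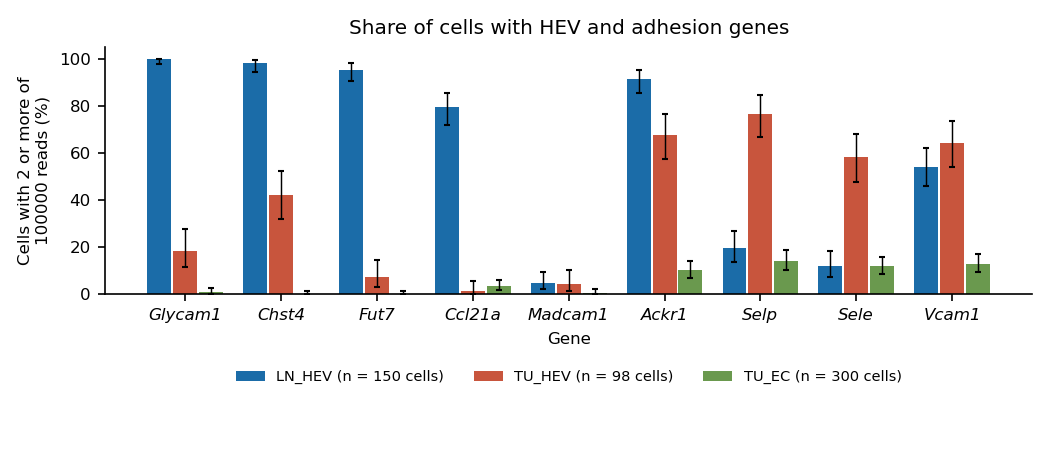
Percent of cells with at least 2 of 100000 counts of each gene in LN_HEV (150 cells), TU_HEV (98) and TU_EC (300), with exact 95% Clopper-Pearson intervals as error bars. Chst4 was found in 98%, 41.8% and 0% of cells, and Selp in 19.3%, 76.5% and 14%. The LN_HEV cells include 10 holding libraries.

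Across TU_HEV cells, the mean expression of the epitope genes with Glycam1 and Madcam1 was set against every other list. Cells with more of these HEV genes had more of the venous list, which holds Selp, and less of the arterial list, which holds Gja4; no coefficient was computed for a single gene. The mean of the Spearman coefficients of both plates was 0.545 with other lymph node HEV genes (0.541 in pool3 over 50 cells and 0.550 in pool4 over 48), against 0.328 for matched random lists. It was 0.539 with the venous and leukocyte adhesion list (0.529 and 0.548), at percentile 97.3 of 1000 random lists. With immune regulatory ligands it was 0.511, with interferon-stimulated genes 0.388 and with MHC class I presentation 0.372. The last pair lay at percentiles 67.5 and 61, inside the bulk of random lists. Arterial genes had -0.279 (-0.292 and -0.265, percentile 0) and tip cell genes -0.164 (0.00924 and -0.337), against 0.214 and 0.211 for random lists. Capillary genes had -0.0495, against 0.324 for random lists (percentile 0.200), and basement membrane genes -0.0365, against 0.356 (percentile 0).

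Clustering within each gate asks what kinds of cell the gate held. All cells that passed the read filters were clustered, before the endothelial rule. Among TU_HEV cells 5 clusters formed, and marker lists named 2 of them. A cluster of 30 cells, from both plates, was led by Cxcl10, with Ackr1 and Cd14 among its leading genes. It had 4 venous genes, 3 epitope genes, 3 other lymph node HEV genes and 6 interferon-stimulated genes at least 2-fold above the other cells. Its leading genes gave it no name. A tip-like cluster of 16 cells, 14 of them within the endothelial rule, came from pool3 (4) and pool4 (12) and was led by Igfbp3 and Nid2. A capillary-like cluster of 9 cells was led by Lpl, Rbp7 and Aqp7 and also held 6 immediate early genes. The other 28 and 18 cells had fewer than 3 markers of any kind, and the 28 cells had 59.6% of the median counts of the gate and 5.39% mitochondrial counts. In TU_EC 7 clusters formed, among them a proliferation-like one of 61 cells and an arterial-like one of 44 cells. A cluster of 43 cells, led by Prnd, Trp53i11 and Pgf, held 11 hypoxia genes and 6 tip cell genes. By the same rule as in TU_HEV, where the tip-like cluster also held 6 tip cell genes, it was tip-like. A venous-like cluster of 29 cells in TU_EC was led by Cd14, Ackr1, Hdc and Selp. It had 9 venous genes, 3 epitope genes and 3 other lymph node HEV genes at least 2-fold above the other TU_EC cells. Ackr1 and Cd14 were also among the leading genes of the TU_HEV cluster of 30 cells, so a part of TU_EC shared these genes. Immediate early genes were also higher in the arterial-like (8 genes) and venous-like (9 genes) clusters of TU_EC. A further 24 cells led by Serpina3f, Cxcl9 and Gbp2 held 9 interferon-stimulated genes, 9 genes of MHC class I presentation and 5 lymphatic markers. The other clusters of TU_EC, of 54 cells each, had no name, with 58.5% and 56.9% of the median counts of the gate and 7.06% mitochondrial counts. In LN_HEV 4 clusters formed, of which 17 cells included the 11 holding libraries. The other 3 split by plate, with 62 of 63, 4 of 41 and 12 of 38 cells from pool2.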

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

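All tests in this part were chosen after the results were seen, except the one on wells with few counts.

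Markers of other cell types appeared in a few cells of the gates, although the gate was set to exclude them. Leukocyte markers (at least 3 of 6 at 10 CPM) were found in 7 LN_HEV cells that passed the read filters, 6 of which had at least 2 T cell markers and 1 at least 2 B cell markers. All 7 also had Glycam1 at 10 CPM or more, with a median of 52417 CPM. By the same measure mural markers were found in 4 TU_EC cells, all with Pdgfrb, Rgs5 and Col1a2, and 2 of these also had at least 2 endothelial genes. These cells were left out by the contaminant rule, and no biological explanation was tested.

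Tumour endothelial genes such as Cd36 and Gpihbp1 appeared in 11 pool1 libraries of LN_HEV, numbered 22 to 38. In each of the 19 pairs, the pool1 library's number equals the leading digits of the TU_HEV library's number, so counts of these TU_HEV libraries may have been added to it when files were joined by name. Tumour cells sorted into the wrong wells, or pairs of cells in a well, would not follow library numbers and are argued against, since 100% of the held pairs share leading digits, against 2.08% of all pairs of a pool1 and a TU_HEV library. After subtraction 7 of the 11 kept over 100000 counts, and Glycam1 stood above 10000 CPM in 6 of these with 0 counts of Cd36. Most pairs that share leading digits were not held, so joining by name alone leaves open why only these libraries were added. The joining step itself is not given in the sources used here.

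Glycam1 and Chst4 stood far below the lymph node level in TU_HEV but above TU_EC. Reads of LN_HEV libraries assigned to TU_HEV libraries of the same number series would bring all abundant genes alike, but Glycam1 stood at 0.198% and Ccl21a at 0.00200% of the LN_HEV level without the holding libraries, a 98.9-fold difference, and Chst4 at 18.8%. Reads spread evenly over the libraries would leave few cells at 0. At a mean of 190.5 Glycam1 counts per cell, 52.0% of TU_HEV cells had 0, which argues against an even spread as the whole source. These values cannot decide about the 28 cells with 1 to 9 counts, nor about reads misassigned unevenly. TU_HEV wells under 50000 counts held on average 0.744% of the Glycam1 counts of an endothelial TU_HEV cell, but also only 0.304% of its total, so their level was 312.5 CPM (64 counts in 1 well), and this test decides nothing. Lymph node HEV cells in the tumour suspension are argued against by Ccl21a, found in 1 of 18 Glycam1-positive TU_HEV cells. A partial HEV state in the tumour remains a hypothesis, and the tissue and the separate set of TU_EC libraries stay open.

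MHC class I presentation genes stood higher in TU_HEV than in TU_EC. Ribosomal RNA and other abundant genes in TU_EC are argued against as the whole cause, since the median under size factors was 1.02, with an SD of 0.226 over plate pairs. In the TU_HEV cells kept, the highest of the 6 leukocyte markers, Coro1a, reached 1.91 CPM, so little leukocyte RNA was seen there. The contaminant rule had already left out cells by these same markers, so this level is no independent test of leukocyte RNA. LN_HEV, which shares the number series of TU_HEV, also stood above TU_EC, with a median of 1.11. TU_HEV and TU_EC share 0 series of library numbers, so a difference between these sets of libraries and the MECA-79 gate cannot be told apart for these genes.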

How the results depend on the processing

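Alternatives without the holding libraries, without ribosomal RNA features and with restricted position genes were chosen after seeing the data; the others were planned. No paired analysis was possible because the labels name no animal and no cell of one group is matched to a cell of another. For values that moved or changed sign under an alternative, the cause was not tested.

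All 60 named genes kept their direction under the 15, 16 and 17 alternatives of the 3 comparisons. Over all alternatives run, 97.5% of the medians of the 21 gene lists kept their sign for TU_HEV against LN_HEV (8 did not), 94.6% for TU_HEV against TU_EC (18 did not) and 95.0% for LN_HEV against TU_EC (6 did not). The lists with a change of sign were the mucins and NF-kB lists against LN_HEV, and the TGF-beta, VEGF receptor, chemokine and junction lists against TU_EC. For LN_HEV against TU_EC 7 lists were run, and those were the capillary, venous and immune regulatory lists. Of its lists outside these 7, MHC class II moved from 0.50 to -0.38 and the mural markers from 2.88 to -1.23 without the holding libraries. Of shares, 82 of 87 stayed within their counting interval.

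Under size factors, without the 20 highest genes and without ribosomal RNA in this order, medians against TU_EC were 0.71, 0.71 and 0.73 for epitope synthesis, 1.49, 1.48 and 1.5 for venous genes, and 1.02, 1.01 and 1.03 for MHC class I. Against LN_HEV the venous median was 0.70 under size factors and 0.64 without the 20 highest genes. The interferon median was 1.74 without the 20 highest genes and 2.49 without the holding libraries. The immune regulatory list of LN_HEV against TU_EC reversed to -1.46 without the holding libraries and to -1.23 without pool1, and reached 1.56 without poolB.

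The position of genes high in LN_HEV was 0.558 with equal weight per cell, 0.48 under size factors, 0.47 without the 20 highest genes, 0.562 under the strict filter, 0.585 without the endothelial rule, 0.54 in thinned cells, 0.52 without the holding libraries, 0.505 without ribosomal RNA, 0.69 with the choosing and measured plates exchanged and 0.53 at 8-fold. That of genes high in TU_EC was 0.37 under size factors, 0.375 without the 20 highest genes and 0.186 without the holding libraries. Leaving out pool1 or pool2 gives no position, since the former chooses the genes and the latter measures them. The Glycam1 share of TU_HEV was 30.6% without thinning. At resolution 0.5 TU_HEV had 3 clusters, and at resolution 2 LN_HEV had 10, TU_HEV 11 and TU_EC 12.

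With each plate left out in turn, the epitope synthesis median against LN_HEV ran from -2.21 to -1.18 (the last without pool2), the tip cell median from 2.15 to 5.29, the venous median from 0.78 to 1.07 and the interferon median from 1.64 to 2.08. Against TU_EC, tip cell genes ran from -4.25 to -1.66, epitope synthesis from 1.06 to 1.27, other lymph node HEV genes from 2.95 to 3.56, venous genes from 1.67 to 2.15 and MHC class I from 1.31 to 1.52. The LN_HEV against TU_EC epitope median ran from 2.34 to 3.06. Positions ran from 0.557 to 0.623 and from 0.272 to 0.396. The Chst4 share of TU_HEV ran from 33.3% to 50.0%, its Glycam1 share from 14.6% to 22.0% and the venous correlation from 0.529 to 0.548. Depth limits genes near the floor of 3 counts: a gene at 0 counts in a group has only a bound.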

Other observations

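The genes in this part were chosen after their values were seen or from a list of receptors and ligands written then. Il6, an inflammatory cytokine, stood at 276.1 CPM in TU_HEV and 27.7 in TU_EC, and in LN_HEV at 42.8 CPM, or 0 without the holding libraries. Csf3, which mobilises neutrophils, stood at 253.2 CPM in TU_HEV, 21.3 in TU_EC and 133.2 in LN_HEV, or 0 without the holding libraries. Il6st, the shared receptor chain of the interleukin 6 family, stood at 1244 CPM in TU_HEV, 1203 in LN_HEV and 170.7 in TU_EC. Its partner Lifr had 525, 627 and 22.4 CPM in the same order. Both MECA-79-positive gates stood above TU_EC for these receptor chains.

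Ifngr1, a chain of the interferon gamma receptor, stood at 599.9 CPM in TU_HEV, 369.98 in LN_HEV and 169.4 in TU_EC. Tnfrsf11a, the receptor of the cytokine RANKL, stood at 58.2, 22.6 and 4.64 CPM. Tnfrsf1a, a receptor of tumour necrosis factor, stood at 404, 264.1 and 205.2 CPM. Il15, which sustains T cells, stood at 64.5, 112.98 and 15.3 CPM, and Cd40, a receptor for T cell help, at 14.4, 0 and 53.1 CPM.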
